A study of Mus musculus with 80 samples.

How the data were processed

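The libraries were RNA-seq of mouse hematopoietic stem cells (HSC) and hematopoietic progenitor cells (HPC), all on the B6 background. The labels' protocols name a Qiagen micro plus kit for RNA and a Clontech kit spelled SMRTr, taken here to be a SMARTer cDNA kit. They state neither how the cDNA was primed, nor the surface markers of the sort, nor the organ. There were 80 libraries in 20 groups, and each library was placed in its group from its own title, age and genotype labels.

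The authors aligned and counted reads with STAR (given as version 3.0.4) and featureCounts 1.4.5 of the Subread package, per the submitters' processing notes. The genome build and annotation release were not given in the sources used here, so genes are named by symbol and Ensembl identifier without coordinates. The authors deposited a first table with the age series and a second with the genotype series. For HPC of the age series and for every genotype library, the deposited values were raw read counts per gene, as whole numbers with a different total in each column. For HSC of the age series, the values the authors deposited were RPKM (reads scaled by exon length and library total), although the table is named as counts. Multiplied by an exon length, each RPKM became a whole multiple of what 1 read is worth. A length giving whole reads in every library was found for 25622 of 25622 detected genes, and 100% of nonzero values came out whole within a tolerance of 1e-05. For 16638 of these genes it was the exon length of GENCODE M21, and for 8984 it was found from the values. The recovered reads made up at least 99.9985% of each library total, which gave the depth of these libraries. The tests had been planned for counts. The first table held 41388 genes and the second 40481, all present in the first, and 40254 identifiers matched a symbol. The table also held 2 rows that were not mouse genes, with at most 0.000144% of the reads of a library, and 1 column of values that was not used.

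Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM factors and the default filter on low counts. RPKM were tested with limma 3.58.1 (robust trend) on log2(TMM-scaled RPKM + 0.5), for genes above 1 RPKM in as many libraries as the smallest group held. A fold change on that scale understates the change of low genes. Comparisons holding HSC and HPC of the age series in a single model (the cell types, and their Adult minus E16 difference) also used limma on this scale, with HPC counts divided by the same lengths. All tests were two-sided, p-values were adjusted over the genes tested by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. The age series of each cell type, the P0 HSC, the P0 HPC and the P14 HPC libraries were each fitted together, without covariates. The 22 comparisons were fixed before the data were examined, as were the gene lists, the rule for named genes, the test of counts and the other settings to be tried. The limma test of the HSC age libraries, and of comparisons that hold them, was chosen after the values were seen.

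The rule named Ifnar1, Ifnar2 and Flt3 in every library. It then named the called genes with the largest changes, with a mean log2 CPM of at least 3 and no overlap between the groups' libraries. These were 10 per direction in 6 main comparisons and 5 in the others. From each gene list with a call, it took up to 4 members of smallest adjusted p. Symbols of predicted genes were left out. A few genes that the rule named are not reported here. Globin genes, H2 genes, Ifit3 and Ifit3b, and the Oas1 genes have near-identical relatives between which reads can be split, and their values are uncertain.

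The 27 gene lists were tested with camera (preset correlation 0.01), adjusted over 594 list-comparison pairs. They covered the interferon response, MHC class I and II presentation, fetal genes of the Lin28b axis, imprinted growth genes, immediate early genes, HSC markers, lymphoid priming, myeloid granules, erythroid and megakaryocyte genes, G2/M and S phase, STAT5 targets, MAPK feedback, NF-kB targets, oxidative phosphorylation, glycolysis and cholesterol synthesis. Lists of hepatocyte, macrophage, endothelial, stroma, B cell, T and NK cell and neutrophil markers stood for other cells a sort could hold, and a last list held Xist and Y-linked genes. Of 228 list calls, 67 held with an estimated correlation, and for the others that p stands beside the call. A list level is the mean log2 value over its members in a library, as log2 CPM with a prior count of 2 or, where limma was used, on the tested RPKM scale, and levels of 2 groups were compared by exact two-sided permutation of the libraries (486 tests, adjusted together). The share of the change from E16 to Adult was computed per library for genes called with an absolute log2 fold change over 1. E16 and Adult also define the gene set, so the shares of other ages are read against them.

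The gene length correlation of a library is Spearman's rho, across genes, between exon length and the library's deviation from the mean of its part of the series. It was taken over genes with a mean log2 CPM above 4, as first looked at. A version over all genes gave weaker correlations, and the minimum was then restored. Genes are not independent replicates, so rho is given as a description. A library was said to hold Y-linked reads above 5 CPM summed over Ddx3y, Eif2s3y, Kdm5d and Uty.

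The smallest library total was 6.95 M (mega) reads. List members were named without a minimum level, and some (Ahsg in HPC of the age series, at a mean log2 CPM of -1.62, or Cd5l in P0 HPC, at 0.11) had few reads, so counting error adds to the spread between libraries there. The labels do not say whether libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. No pair of libraries within a group was identical (0 of 123 pairs), and the smallest chi-square per degree of freedom was 5.185, over genes with at least 10 reads in the pair. HSC libraries carried code prefixes in their titles. E14, E16 and E18 shared one, P7 and P14 another, and P0 and Adult yet another, while each HPC age had its own. Whether a prefix marks a run is not stated.

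Each test was tried on simulated counts with 200 changed genes, drawn from the mean levels, dispersions and totals of the real libraries, with changed genes expected above 50 reads. Of genes changed 2-fold or 4-fold, 58% and 89% were recovered for HSC Adult against E16 (12692 genes), 75% and 99% for the knockout in P0 HSC (15885 genes), 77% and 100% in P0 HPC (12749 genes), 52% and 92% for Flt3 ITD in heterozygotes (17120 genes), and 12% and 74% for the difference between Flt3 ITD effects (17080 genes). Between 1 and 19 unchanged genes were called per comparison.

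Also tried, as fixed at the start, were DESeq2 1.42.0, RLE factors, no filter or a strict filter (CPM above 10), only the groups compared, a replicate block, each library left out, fry and an estimated correlation for lists, a prior count of 0.5, and a log2 fold threshold of 2. Chosen after seeing the data were edgeR on the recovered reads, pseudocounts of 0.1 and 1, no scaling of the RPKM, the length correlation or the Y-linked level as a covariate, a fit of libraries with a length correlation above -0.3, the comparisons within a code prefix, and the overlaps of calls between comparisons. Tables were prepared with Python 3.11.15 (pandas 2.3.3, numpy 2.4.6), and figures drawn with matplotlib 3.10.9.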

Results

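RNA of mouse hematopoietic stem cells (HSC) was sequenced at 7 ages, at embryonic days E14, E16 and E18 (named by their whole day), at postnatal days P0, P7 and P14, and at 8 weeks (Adult). Hematopoietic progenitor cells (HPC) were sequenced at 5 of these ages. Cells labelled Ifnar knockout were compared with wild type at P0. At P14, HPC were compared across labelled Ifnar genotype (heterozygote or knockout) and Flt3 genotype (wild type, or heterozygous for an internal tandem duplication, ITD). There were 26 HSC and 20 HPC libraries of the age series, 9 HSC and 8 HPC libraries of the P0 genotypes, and 17 HPC libraries at P14. Depth in M (mega) reads ran from 6.95 to 24.034 in HSC and 7.911 to 25.382 in HPC of the age series, from 37.039 to 46.303 in P0 HSC and 11.683 to 14.72 in P0 HPC of the genotype series, and it was at least 58.4 at P14.

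Between E16 and 8 weeks, HSC lost RNA of fetal growth genes and gained RNA of antigen presentation and megakaryocyte genes. The genes of the Lin28b axis, which holds fetal RNA-binding proteins and their targets, fell as a whole. Genes for MHC class I and class II rose, as did platelet integrins. Of 13375 genes tested with limma (4 libraries against 4), 1631 were called higher in Adult and 1674 lower.

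Hmga2, a chromatin protein of fetal HSC, fell by 3.53 ± 0.12 on the log2 scale (1.79 ± 0.21 in Adult, 5.32 ± 0.14 at E16; limma adjusted p = 1.54e-17). The RNA-binding proteins Igf2bp1 and Igf2bp3 fell by 5.24 ± 0.22 and 4.27 ± 0.22 on the log2 scale (limma adjusted p = 5.17e-16 and 4.95e-14). All 8 tested members of the Lin28b axis fell (8 adjusted over the list alone; camera adjusted p = 4.2e-16). Of the imprinted growth genes, 6 of 8 fell (6 adjusted over the list alone; camera adjusted p = 2.02e-07). Among them were the noncoding H19 (-5.79 ± 0.22; limma adjusted p = 4.85e-17), the growth factor Igf2 (-3.86 ± 0.2; limma adjusted p = 3.29e-14) and the adaptor Grb10 (-1.22 ± 0.15).

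Interferon-response genes rose in 38 of 58 members (40 adjusted over the list alone; camera adjusted p = 6.89e-16, and adjusted p = 0.0833 with an estimated correlation). Their list level went from 3.25 ± 0.11 to 4.08 ± 0.13 (exact permutation p = 0.02857, the smallest possible). The exonuclease Isg20 rose by 1.94 ± 0.17, Ifi27 by 1.83 ± 0.16 and the surface protein Ly6e by 1.14 ± 0.1 (limma adjusted p = 9.29e-10, 1.32e-09 and 4.92e-10). MHC class I rose in 16 of 18 members (16 adjusted over the list alone; camera adjusted p = 2.45e-22) and MHC class II in 7 of 8 (7 adjusted over the list alone; camera adjusted p = 1.84e-11). The H2 genes had larger values (H2-Q6 6.74 ± 0.28, H2-Aa 5.98 ± 0.34), which are uncertain because reads can be split between near-identical relatives. The largest other gains were the sulfotransferase Sult1a1 (6.06 ± 0.45), the phosphodiesterase Gdpd3 (5.95 ± 0.34), the retinal dehydrogenase Aldh1a1 (5.89 ± 0.4), the light chain Myl10 (5.78 ± 0.38) and Sdsl (5.56 ± 0.27), each at a limma adjusted p of 5.55e-11 or lower.

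Megakaryocyte genes rose in 6 of 12 members, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0023). The integrins Itgb3 and Itga2b gained 3.18 ± 0.26 and 3.01 ± 0.24, and the platelet chemokine Pf4 gained 3.13 ± 0.27 (limma adjusted p = 1.3e-09). Lymphoid priming fell in 7 of 10 members (9 adjusted over the list alone; camera adjusted p = 4.59e-06), with Flt3, the receptor of lymphoid-primed cells, at -1.32 ± 0.24. Cd48, a surface protein sparse on HSC, fell by 2.09 ± 0.26 on the log2 scale (limma adjusted p = 6.84e-07). HSC markers went both ways (5 higher and 9 lower of 20, the same adjusted over the list alone, camera adjusted p = 0.63). Myeloid granule genes were higher in 1 and lower in 5 of 14 (1 and 6 adjusted over the list alone; camera adjusted p = 0.0122, and adjusted p = 0.371 with an estimated correlation), with Mpo, the neutrophil peroxidase, at -4.64 ± 0.68. Erythroid genes were higher in 3 and lower in 8 of 15 (4 and 8 adjusted over the list alone; camera adjusted p = 0.177), and the factor Gata1 gained 1.83.

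G2/M genes fell in 18 of 20 members (18 adjusted over the list alone; camera adjusted p = 5.73e-14, and adjusted p = 0.0532 with an estimated correlation), including the ubiquitin conjugase Ube2c (-1.74 ± 0.15) and the kinase Plk1 (-1.8 ± 0.19). S phase had 1 higher and 12 lower of 18 (1 and 15 adjusted over the list alone; camera adjusted p = 9.97e-06, and adjusted p = 0.311 with an estimated correlation). Oxidative phosphorylation had 1 higher and 8 lower of 21 (1 and 10 adjusted over the list alone; camera adjusted p = 0.00365, and adjusted p = 0.239 with an estimated correlation). Glycolysis had 2 higher and 5 lower of 15 (camera adjusted p = 0.051). Cholesterol synthesis had 1 lower of 17, with a median of 0.106 while the camera sign was down (camera adjusted p = 0.96). STAT5 targets had 3 higher and 1 lower of 9 (4 and 1 adjusted over the list alone; camera adjusted p = 0.168), with the cytokine inhibitor Cish at 3.14 ± 0.18 (limma adjusted p = 3.32e-13). MAPK feedback had 2 higher of 7, NF-kB targets 3 higher of 13, and immediate early genes 1 higher and 3 lower of 12 (camera adjusted p = 0.278, 0.182 and 0.483).

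Markers of other cells were also read. Macrophage markers rose in 6 of 8 and fell in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00141, and adjusted p = 0.103 with an estimated correlation). Vcam1 gained 4.1 ± 0.45 (3.6 ± 0.27 in Adult, -0.49 ± 0.38 at E16) and the complement gene C1qb 3.71 ± 0.52, while Cd68 fell by 0.72 ± 0.15 on the log2 scale. Endothelial markers had 3 lower of 5, stroma 1 higher of 3, B cell 1 lower of 3 and T and NK cell 1 higher of 2 (camera adjusted p = 0.153, 0.126, 0.309 and 0.235). Hepatocyte markers had 2 higher of 5, with a median of -0.038 and an upward camera sign (camera adjusted p = 0.347). Neutrophil markers had none called of 6 by limma (camera adjusted p = 0.846). The sex-linked list had 1 higher and 4 lower of 5 (camera adjusted p = 0.0455, and adjusted p = 0.342 with an estimated correlation). Y-linked reads were found in 0 of 4 Adult and 4 of 4 E16 libraries, and Ddx3y fell by 4.63 ± 0.85 on the log2 scale. With the Y-linked level in the model, limma called 1868 genes. Adult and E16 libraries had different code prefixes. Adult against P0, which share one, gave 2835 limma calls, and 1576 of the Adult against E16 calls were called there in the same direction.

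HSC at E16 and E14 differed in few genes. Those higher at E16 included the calcium-binding S100a4 (1.26 ± 0.22; limma adjusted p = 0.0161), Clip3 (1.1 ± 0.16; limma adjusted p = 0.00207), the immune receptor Ly9 (1.02 ± 0.2; limma adjusted p = 0.0384) and the urea transporter Slc14a1 (0.92 ± 0.17; limma adjusted p = 0.0208). In all, limma called 7 higher and 0 lower of 13375 (812 at an unadjusted p under 0.05), against 0 by limma with only these groups fitted and 64 by DESeq2. Erythroid genes rose in 2 of 15, both alpha-globin genes with uncertain values (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.04e-06). Without E16 replicate 3 or 4, limma called 2 genes, and without E14 replicates 1 and 3, limma called 3 and 4.

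At E18, HSC had a far stronger interferon response than at E16. Antiviral effectors, their transcription factor Irf7 and the MHC class I machinery rose together, while G2/M genes fell. Cholesterol synthesis genes and STAT5 targets rose over the same interval. Of 13375 genes, limma called 326 higher and 410 lower (3 libraries against 4).

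The interferon response list rose in 47 of 58 members (52 adjusted over the list alone; camera adjusted p = 3.96e-67), and their list level went from 3.25 ± 0.11 at E16 to 4.59 ± 0.31 at E18 (exact permutation p = 0.02857, the smallest possible). Ifi44 gained 2.79 ± 0.26 (limma adjusted p = 3.87e-08), the GTPase Iigp1 2.67 ± 0.28 (limma adjusted p = 6.41e-07) and Ifit1, which binds viral RNA, 2.57 ± 0.33 (limma adjusted p = 1.19e-05). Irf7 gained 2.48 ± 0.24 and the receptor transporter Rtp4 2.43 ± 0.19 (8.43 ± 0.36 at E18, 6 ± 0.3 at E16; limma adjusted p = 4.92e-09). MHC class I rose in 8 of 18 (12 adjusted over the list alone; camera adjusted p = 5.3e-12), with B2m at 1.17 ± 0.11 and the peptide transporter Tap1 at 1 ± 0.18. Macrophage markers rose in 1 of 8 (camera adjusted p = 0.109), C1qb at 1.9 ± 0.56.

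G2/M genes fell in 14 of 20 (20 adjusted over the list alone; camera adjusted p = 8.71e-19) and S phase in 11 of 18 (15 adjusted over the list alone; camera adjusted p = 6.53e-14, and adjusted p = 0.0677 with an estimated correlation). Cholesterol synthesis rose in 8 of 17 (13 adjusted over the list alone; camera adjusted p = 2.21e-08). STAT5 targets rose in 3 of 9 (6 adjusted over the list alone; camera adjusted p = 2.94e-05), with Socs2 at 1.33 ± 0.21 and Cish at 0.99 ± 0.2. Erythroid genes fell in 3 of 15 (8 adjusted over the list alone; camera adjusted p = 5.3e-05), with Gata1 at -2.41 ± 0.47. Cd48 fell by 3.52 ± 0.28 on the log2 scale (1.69 ± 0.81 at E18, 5.21 ± 0.36 at E16; limma adjusted p = 4.92e-09). Limma called 450 genes without E18 replicate 1, 425 without E18 replicate 2, and 435 and 441 without E16 replicates 3 and 4. Y-linked reads were found in 2 of 3 E18 libraries and 4 of 4 at E16, and with the length correlation in the model limma called 462 genes.

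**Figure D1:**
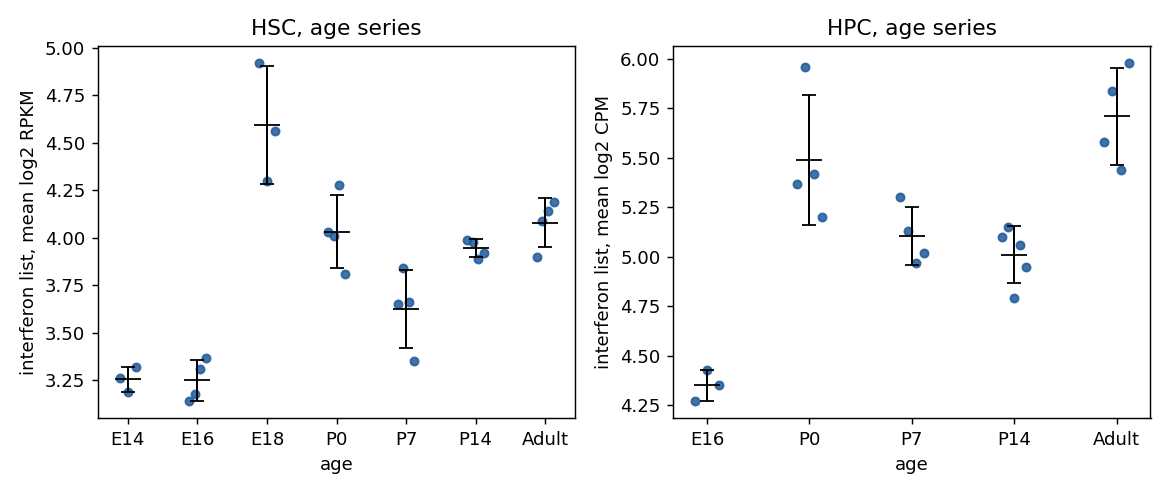
Level of the interferon response list by age in HSC (log2 RPKM) and HPC (log2 CPM). Each dot is a library, and bars give the mean ± SD of the group.

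At birth some interferon-response genes of HSC fell, while Cd48 and lymphoid genes rose. Of 13375 genes, limma called 373 higher and 278 lower at P0 than at E18. The ubiquitin-like Isg15 fell by 1.3 ± 0.24 on the log2 scale (limma adjusted p = 0.0016). The interferon genes fell in 17 of 58 (34 lower and 1 higher adjusted over the list alone; camera adjusted p = 4.19e-19, and adjusted p = 0.0566 with an estimated correlation). Cd48 gained 3.29 ± 0.28 (limma adjusted p = 4.16e-08). Lymphoid priming rose in 3 of 10 (3 adjusted over the list alone; camera adjusted p = 4.54e-05), with Flt3 at 0.97 ± 0.26. Glycolysis fell in 6 of 15 (7 adjusted over the list alone; camera adjusted p = 2.6e-06, and adjusted p = 0.112 with an estimated correlation). Imprinted growth genes fell in 3 of 8 (4 adjusted over the list alone; camera adjusted p = 0.00301), with H19 at -1.52 ± 0.23. Limma called 383 genes without E18 replicate 2 and 388 without P0 replicate 3.

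From P0 to P7, genes of the Lin28b axis went on falling in HSC. Fabp4, a fatty acid carrier, gained 6.84 ± 0.44 (5.97 ± 1.07 at P7, -0.87 ± 0.25 at P0; limma adjusted p = 4.31e-11), Gdpd3 5.93 ± 0.34 and the matrix protein Sparc 3.84 ± 0.43. Over the same interval stroma markers went from a list level of -0.17 ± 0.17 to 0.63 ± 0.38 (1 of 3 higher, camera adjusted p = 0.149). Endothelial markers went from 2.25 ± 0.16 to 2.72 ± 0.36 (2 of 5 higher, with a median of -0.009 and an upward camera sign, camera adjusted p = 0.206). Limma called 475 genes higher and 343 lower of 13375. The Lin28b axis fell in 3 of 8 (4 adjusted over the list alone; camera adjusted p = 5.9e-06), with Igf2bp1 at -2.26 ± 0.22, and H19 lost 2.3 ± 0.22. Genes of interferon response fell in 12 of 58 (19 adjusted over the list alone; camera adjusted p = 4.77e-09, and adjusted p = 0.239 with an estimated correlation), with Irf7 at -1.57 ± 0.22. S phase rose in 7 of 18 (13 adjusted over the list alone; camera adjusted p = 1.98e-09, and adjusted p = 0.152 with an estimated correlation), with Tyms, which makes thymidylate, at 0.63 ± 0.13. Cholesterol synthesis fell in 5 of 17 (9 adjusted over the list alone; camera adjusted p = 5.25e-08), with Msmo1 at -0.97 ± 0.17. Lymphoid priming fell in 3 of 10 (5 adjusted over the list alone; camera adjusted p = 0.00018), with Flt3 at -1.11 ± 0.24. Limma called 463 genes without P7 replicate 1 and 516 without P0 replicate 3.

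Between P7 and P14, mitotic genes of HSC fell and MHC genes rose. The class II chaperone Cd74 gained 1.76 ± 0.28 (limma adjusted p = 0.00127), and the glucocorticoid-responsive Tsc22d3 and Per1 gained 1.66 ± 0.21 and 1.72 ± 0.29. Limma called 79 genes higher and 153 lower of 13375. G2/M genes fell in 15 of 20 (17 adjusted over the list alone; camera adjusted p = 1.19e-21), with Ube2c at -0.8 ± 0.15 and Birc5 at -0.77 ± 0.14. S phase fell in 3 of 18 (10 adjusted over the list alone; camera adjusted p = 2.94e-14, and adjusted p = 0.0661 with an estimated correlation). MHC class I rose in 5 of 18 (8 adjusted over the list alone; camera adjusted p = 4.68e-09) and class II in 3 of 8 (5 adjusted over the list alone; camera adjusted p = 1.46e-05). Interferon-response genes rose in 2 of 58 (12 adjusted over the list alone; camera adjusted p = 2.48e-10, and adjusted p = 0.199 with an estimated correlation). Fetal Lin28b-axis genes fell in 3 of 8 (4 adjusted over the list alone; camera adjusted p = 0.000124), with Igf2bp3 at -1.13 ± 0.22. Y-linked reads were found in 4 of 4 P7 and 2 of 4 P14 libraries. Limma called 124 and 148 genes without P7 replicates 1 and 4, and 139 and 141 without P14 replicates 1 and 3.

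From P14 to 8 weeks, HSC lost more of the fetal axis and gained platelet integrins and class II genes. Itgb3 and Itga2b gained 2.45 ± 0.26 and 2.08 ± 0.24 (limma adjusted p = 2.87e-07 and 1.88e-06). Limma called 307 genes higher and 403 lower of 13375. The Lin28b axis fell in 5 of 8 (8 adjusted over the list alone; camera adjusted p = 1.9e-14), with Igf2bp3 at -2.47 ± 0.22 and Hmga2 at -1.23 ± 0.12. MHC class II rose in 7 of 8 (7 adjusted over the list alone; camera adjusted p = 3.25e-10) and class I in 7 of 18 (9 adjusted over the list alone; camera adjusted p = 1.77e-09). Megakaryocyte genes were higher in 3 and lower in 1 of 12 (camera adjusted p = 0.000408). The interferon response list rose in 4 of 58 (4 adjusted over the list alone; camera adjusted p = 0.0897). Myl10 gained 4.59 ± 0.38 and Aldh1a1 4.5 ± 0.4, while Sparc and Fabp4, which had risen at P7, fell by 3.75 ± 0.43 and 3.14 ± 0.44 on the log2 scale.

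Across these ages, HSC moved toward the adult. For the lower genes, E18 and P0 libraries overlapped (21.98 to 29.98% and 20.37 to 28.47%), so a move back is not shown. For the 746 genes higher in Adult than at E16 by more than 1 on the log2 scale, the median share of the change reached was -4.162% at E14, 24.57% at E18, 34.82% at P0, 46.35% at P7 and 66.33% at P14. For the 514 lower genes the shares were 0.8693%, 29.25%, 23.91%, 39.29% and 64.03%. With a log2 fold threshold of 2, the shares of lower genes were -1.909% at E14, 19.53% at E18 and 12.91% at P0. In HPC, the shares of 1302 higher genes were 32.33% at P0, 51.87% at P7 and 48.02% at P14, and those of 691 lower genes 19.8%, 38.15% and 50.33%. All shares are measured against the same E16 libraries that define the set.

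**Figure D2:**
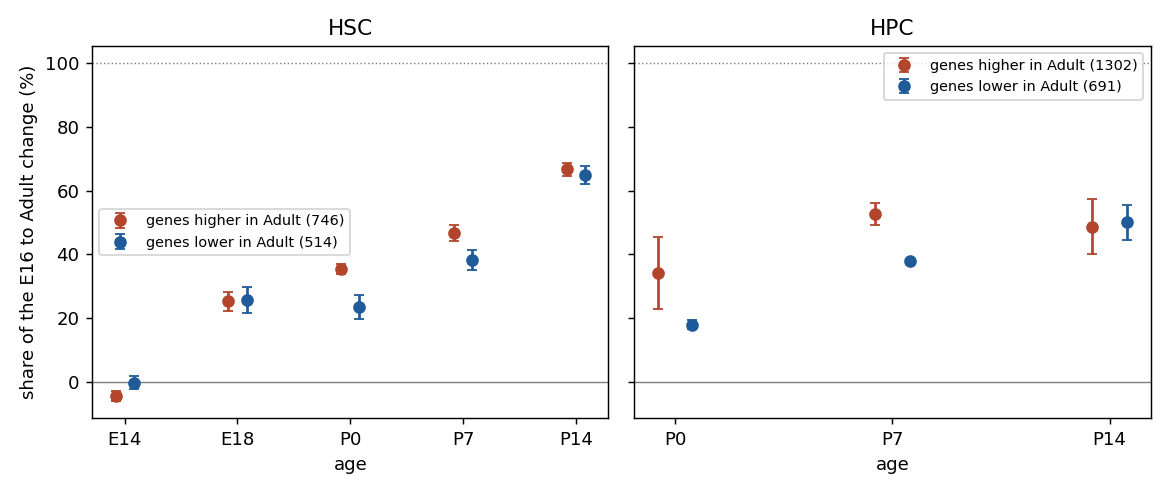
Percent of the change from E16 to Adult reached at each age, for genes higher or lower in Adult by more than 1 on the log2 scale, in HSC and HPC. Points are means of libraries and bars their SD.

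HPC, like HSC, lost RNA of fetal growth genes and gained MHC class I between E16 and 8 weeks. Dntt, the template-free polymerase of antigen receptor joining, rose from 1.6 ± 0.22 to 9.81 ± 0.35 (8.27 ± 0.4; edgeR adjusted p = 8.69e-13). Of 14754 genes, edgeR called 2202 higher in Adult and 1777 lower (4 libraries against 3). Fetal Lin28b-axis genes fell in 8 of 8 (8 adjusted over the list alone; camera adjusted p = 7.1e-54), with Igf2bp3 at -5.7 ± 0.21 and Igf2bp2 at -4.6 ± 0.2. Imprinted growth genes fell in 7 of 10 (7 adjusted over the list alone; camera adjusted p = 1.3e-10), with H19 at -8.24 ± 0.55 and Grb10 at -3.07 ± 0.2. The interferon genes rose in 49 of 58 (51 adjusted over the list alone; camera adjusted p = 6.93e-24, and adjusted p = 0.0696 with an estimated correlation), with Ifi44 at 4.58 ± 0.41 and Isg20 at 1.94 ± 0.19. MHC class I rose in 14 members (14 adjusted over the list alone; camera adjusted p = 1.08e-21). G2/M genes fell in 17 (18 adjusted over the list alone; camera adjusted p = 6.84e-17, and adjusted p = 0.0661 with an estimated correlation), with the cyclin Ccnb1 at -1.84 ± 0.18. Lymphoid priming was higher in 4 and lower in 5 of 15, with a median of -0.278 and an upward camera sign (camera adjusted p = 0.451). Macrophage markers rose in 7 of 9 (camera adjusted p = 0.000986, and adjusted p = 0.25 with an estimated correlation), with Vcam1 at 5.73 ± 0.9. B cell markers fell in 5 of 7 (camera adjusted p = 0.0174, and adjusted p = 0.482 with an estimated correlation). Without E16 replicate 2, edgeR called 2535 genes. Each HPC age had its own code prefix, so age and prefix cannot be told apart.

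The calls in HSC and HPC overlapped. Among 12551 genes tested in both, 806 were higher in Adult in both (233 if independent), 808 lower in both (211 if independent), and 55 were called in opposite directions.

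By P0, HPC had already gained the interferon response. Irf7 gained 2.4 ± 0.26 (7.22 ± 0.46 at P0, 4.86 ± 0.23 at E16; edgeR adjusted p = 1.39e-05). The mast cell proteases Cma1, Tpsb2 and Cpa3 gained 5.57 ± 1.32, 5.5 ± 1.41 and 4.94 ± 0.81 (edgeR adjusted p = 0.0296, 0.0448 and 0.003), with Hdc, which makes histamine, at 3.53 ± 0.82. Of 14754 genes, edgeR called 384 higher and 101 lower. Genes of interferon response rose in 34 of 58 (46 adjusted over the list alone; camera adjusted p = 1.19e-49), from a list level of 4.35 ± 0.08 to 5.49 ± 0.33. MHC class I rose in 4 (10 adjusted over the list alone; camera adjusted p = 2.52e-09). The Lin28b axis fell in 1 of 8 (3 adjusted over the list alone; camera adjusted p = 1.68e-05), Igf2bp1 at -2.84 ± 0.29, and imprinted growth genes in 2 of 10 (4 adjusted over the list alone; camera adjusted p = 1.27e-05). Dntt gained 1.74 ± 0.32. The liver gene Ahsg gained 6.91 ± 1.23, with hepatocyte markers higher in 1 of 7 (2 adjusted over the list alone; camera adjusted p = 0.00398, and adjusted p = 0.0974 with an estimated correlation). Macrophage markers had 0 of 9 called by edgeR (6 higher adjusted over the list alone; camera adjusted p = 7.14e-05, and adjusted p = 0.142 with an estimated correlation). EdgeR called 232 and 254 genes without E16 replicates 1 and 2, and 283 and 244 without P0 replicates 2 and 3. With the length correlation in the model, edgeR called 926.

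Between P0 and P7, Dntt rose by a further 4.09 ± 0.28 in HPC (edgeR adjusted p = 4e-09), while genes of the Lin28b axis fell. Igf2bp1 fell by 5.78 ± 0.4, the mast cell genes Cpa3 by 3.26 ± 0.66 and Hdc by 4.29 ± 0.75 on the log2 scale. Of 14754 genes, edgeR called 84 higher and 134 lower. Fetal Lin28b-axis genes fell in 3 of 8 (4 adjusted over the list alone; camera adjusted p = 5.91e-16), and H19 lost 3.03 ± 0.41. Interferon-response genes fell in 5 of 58 (12 adjusted over the list alone; camera adjusted p = 2.78e-10, and adjusted p = 0.277 with an estimated correlation), with Irf7 at -1.4 ± 0.22. Hepatocyte markers fell in 2 of 7 (3 adjusted over the list alone; camera adjusted p = 0.000178), with Ahsg at -4.82 ± 0.86. EdgeR called 119, 112, 140 and 126 genes without P7 replicates 1, 2, 3 and 4, and 144 without P0 replicate 2. EdgeR called 369 with the length correlation in the model.

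At P14, HPC had higher levels of several granule genes. The eosinophil genes Epx and Prg2 gained 6.64 ± 1.31 and 5.79 ± 1.35 (edgeR adjusted p = 0.00667 and 0.016), the neutrophil elastase gene Elane 5.72 ± 1.18 and the factor Cebpe 4.77 ± 0.65. Of 14754 genes, edgeR called 712 higher and 746 lower than at P7. Myeloid granule genes rose in 8 of 15 (10 adjusted over the list alone; camera adjusted p = 4.01e-08, and adjusted p = 0.105 with an estimated correlation), with Mpo at 2.76 ± 0.42. MHC class I rose in 6 (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.03e-06). HSC markers were higher in 1 and lower in 6 of 20 (camera adjusted p = 0.000351, and adjusted p = 0.0974 with an estimated correlation). B cell markers were higher in 1 of 7 and macrophage markers in 2 of 9 (camera adjusted p = 0.023 and 0.0414, and adjusted p = 0.492 and 0.47 with an estimated correlation), and the B cell level went from 1.51 ± 0.33 to 2.66 ± 0.55. The P14 libraries had length correlations of -0.52, -0.58, 0.13, 0.27 and -0.03, and 1 of 5 held Y-linked reads against 4 of 4 at P7. EdgeR called 2422 genes with the length correlation in the model and 417 with the Y-linked level. EdgeR called 542, 890, 873 and 797 genes without P7 replicates 1, 2, 3 and 4, and 962 without P14 replicate 3.

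From P14 to 8 weeks these granule genes fell again in HPC. Elane and Epx fell by 5.41 ± 1.16 and 5.4 ± 1.22 on the log2 scale, and Mpo by 3.14 ± 0.43 (edgeR adjusted p = 4.84e-05). Neutrophil markers were lower in 2 of 7, Ltf and Mmp8, and B cell markers in 3 of 7 (camera adjusted p = 0.0444 and 0.0157, and adjusted p = 0.492 and 0.473 with an estimated correlation). Of 14754 genes, edgeR called 2202 higher and 2072 lower. The interferon response list was higher in 35 and lower in 1 of 58 (40 higher adjusted over the list alone; camera adjusted p = 3.41e-09, and adjusted p = 0.316 with an estimated correlation). The Lin28b axis fell in 6 of 8 (camera adjusted p = 3.28e-19), with Igf2bp3 at -4.99 ± 0.2. G2/M genes fell in 14 (15 adjusted over the list alone; camera adjusted p = 2.66e-07, and adjusted p = 0.252 with an estimated correlation). The Adult length correlations were 0.48, 0.17, 0.28 and 0.41. Without the 3 HPC libraries below -0.3 (2 at P14 and P7 replicate 4) edgeR called 2258 genes, and with the length correlation in the model 1930.

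Averaged over the 5 shared ages, HSC had more stem cell and megakaryocyte RNA and HPC more lymphoid RNA. No code prefix was shared, so cell type and prefix cannot be told apart. Of 14320 genes, limma called 4315 higher in HSC and 4962 lower. All 20 HSC markers were higher (20 adjusted over the list alone; camera adjusted p = 1.36e-20), with the fusion-partner gene Mllt3 at 2.86 ± 0.06 (limma adjusted p = 1.67e-34) and the junction protein Esam at 2.73 ± 0.06. All 12 megakaryocyte genes were higher (12 adjusted over the list alone; camera adjusted p = 9.97e-06), with Vwf at 2.57 ± 0.09, and so were 7 of 8 imprinted growth genes (camera adjusted p = 5.94e-06), with Grb10 at 2.62 ± 0.07. Lymphoid priming was lower in 14 of 14 (14 adjusted over the list alone; camera adjusted p = 7.77e-15), with Dntt at -6.06 ± 0.12, Ighm at -6.94 ± 0.2 and Flt3 at -2.13 ± 0.17. Myeloid granule genes had 3 higher and 10 lower of 15 (3 and 10 adjusted over the list alone; camera adjusted p = 0.0104, and adjusted p = 0.402 with an estimated correlation), with Mpo at -6.17 ± 0.28. G2/M genes were lower in 19 of 20 (camera adjusted p = 1.1e-10, and adjusted p = 0.0948 with an estimated correlation). The interferon genes were higher in 28 and lower in 12 (camera adjusted p = 0.105).

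The change from E16 to Adult differed between the cell types in 605 of 14320 genes by limma, 282 with a higher and 323 with a lower change in HSC. Megakaryocyte genes had 7 higher and 1 lower of 12 (camera adjusted p = 1.32e-08), with Itgb3 at 2.97 ± 0.36 and Pf4 at 2.98 ± 0.5. Gata1, of the erythroid list, stood at 3.22 ± 0.67. Lymphoid priming had 1 higher and 6 lower of 14 (2 and 8 adjusted over the list alone; camera adjusted p = 3.79e-06), with Dntt at -6.95 ± 0.39 (limma adjusted p = 6.81e-17). Genes of interferon response had 1 higher and 5 lower (6 lower adjusted over the list alone; camera adjusted p = 0.00294, and adjusted p = 0.57 with an estimated correlation). Igf2 (-2.54 ± 0.3) and H19 (-1.06 ± 0.31) had the opposite sign with edgeR on recovered reads (1.02 and 1.93).

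In cells labelled Ifnar knockout, edgeR called 0 changes in the receptor genes Ifnar1 and Ifnar2, though these tests do not exclude one. At P0, Ifnar1 (ENSMUSG00000022967) was at 5.96 ± 0.19 in wild type and 6.04 ± 0.08 in labelled knockout HSC (edgeR adjusted p = 0.872), and at 5.94 ± 0.25 and 6.37 ± 0.09 in HPC (edgeR adjusted p = 0.0735). Ifnar2 (ENSMUSG00000022971) was at 5.05 ± 0.34 and 5.2 ± 0.2 in HSC, and 6.28 ± 0.23 and 6.38 ± 0.26 in HPC (edgeR adjusted p = 0.864 and 0.727). At P14, Ifnar1 was at 5 ± 0.56 in heterozygotes and 5.74 ± 0.13 in labelled knockouts with wild-type Flt3, and at 5.7 ± 0.12 and 5.61 ± 0.12 with Flt3 ITD (edgeR adjusted p = 0.0549 and 0.853). Ifnar2 was at 4.22 ± 0.78, 5.01 ± 0.38, 5.13 ± 0.16 and 4.28 ± 0.53 in the same order (edgeR adjusted p = 0.201 and 0.191). The labels name no subunit or allele, and a gene-level count does not test a deletion of part of a gene. Flt3 (ENSMUSG00000042817) was at 7.82 ± 1.5 and 8.94 ± 0.11 in heterozygotes without and with ITD, and 9.64 ± 0.45 and 7.89 ± 0.85 in knockouts (edgeR adjusted p = 0.672 and 0.297). The count does not tell the duplicated allele apart. At P0, Flt3 was at 8.16 ± 0.47 and 8.79 ± 0.45 in wild type and labelled knockout HSC, and 9.34 ± 0.44 and 9.12 ± 0.37 in HPC (edgeR adjusted p = 0.39 and 0.538).

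HSC labelled Ifnar knockout at P0 had far less of the interferon response. Antiviral effectors, their inducer Irf7 and class I presentation fell together. Of 16224 genes, edgeR called 34 higher and 152 lower (4 libraries against 5). Of the 152, 63 were in the interferon or class I lists. Interferon-response genes fell in 52 (57 adjusted over the list alone; camera adjusted p = 6.42e-298), from a list level of 5.92 ± 0.37 to 3.07 ± 0.2 (exact permutation p = 0.007937, the smallest possible). Rtp4 went from 7.94 ± 0.5 to 0.94 ± 0.6 (-7.01 ± 0.35; edgeR adjusted p = 9.08e-08), Ifi44 fell by 8.04 ± 0.46 and the protease Usp18, which restrains the receptor, by 5.56 ± 0.42 on the log2 scale. Ifit1 fell by 5.09 ± 0.4 and Irf7 by 4.66 ± 0.33 on the log2 scale. MHC class I fell in 11 (13 adjusted over the list alone; camera adjusted p = 4.78e-73), with Tap1 at -1.82 ± 0.11. Macrophage markers fell in 3 of 9 (6 adjusted over the list alone; camera adjusted p = 8.24e-07, and adjusted p = 0.247 with an estimated correlation), with Vcam1 at -2.29 ± 0.37 and Cd5l at -2.38 ± 0.42. Y-linked Ddx3y was at 6.05 ± 0.14 in wild type and 6.67 ± 0.34 in knockouts. Xist was at 4.97 ± 0.69 and 3.76 ± 2.84, and knockout replicate 4 held almost none (-0.41).

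**Figure D3:**
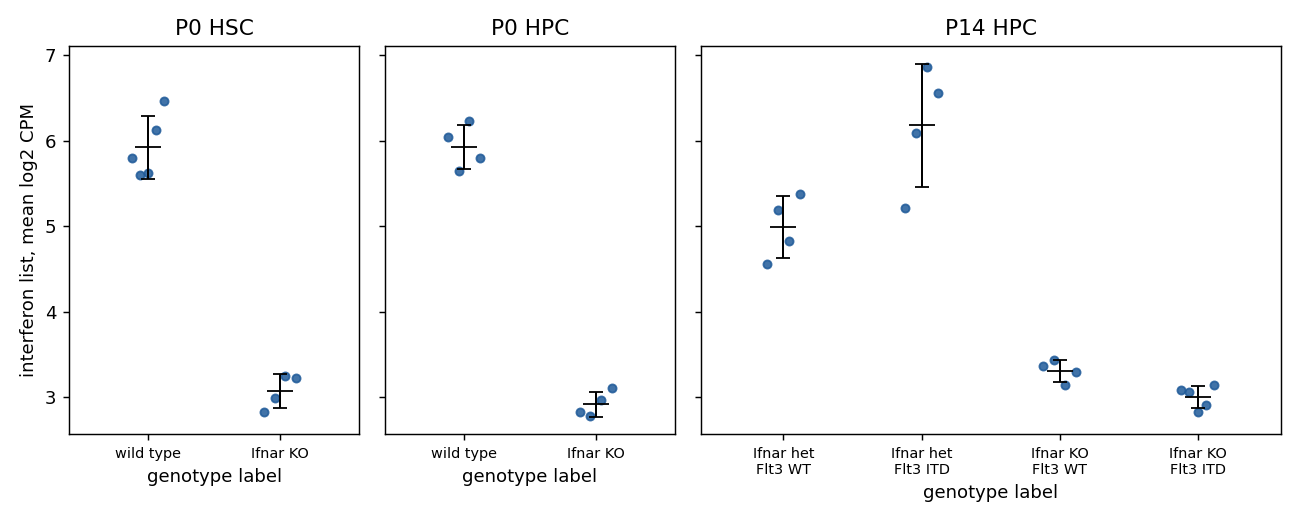
Level of the interferon response list (log2 CPM) in each genotype group at P0 and P14. Each dot is a library, and bars give the mean ± SD of the group.

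HPC labelled Ifnar knockout at P0 had far less of the interferon response and also differed in lineage genes. The lymphoid list was lower. Of 12988 genes, edgeR called 675 higher and 725 lower (4 libraries against 4). Rtp4 fell by 6.47 ± 0.26 on the log2 scale (2.28 ± 0.48 against 8.74 ± 0.34; edgeR adjusted p = 4.3e-08), Ifit1 by 6.09 ± 0.35 and Irf7 by 5.26 ± 0.26. The interferon response list fell in 56 (58 adjusted over the list alone; camera adjusted p = 1.17e-171) and MHC class I in 14 of 16 (14 adjusted over the list alone; camera adjusted p = 6.17e-27), with B2m at -1.67 ± 0.11. These lists held 70 of the 725 lower genes.

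Lymphoid priming fell in 13 of 15 (13 adjusted over the list alone; camera adjusted p = 1.41e-20), from a list level of 6.8 ± 0.06 to 5.28 ± 0.15 (exact permutation p = 0.02857, the smallest possible). Ccr9 fell by 2.4 ± 0.14, the recombinase gene Rag2 by 2.69 ± 0.29 and Ighm by 3.15 ± 0.22 on the log2 scale. B cell markers fell in 6 of 7 (7 adjusted over the list alone; camera adjusted p = 2.17e-07, and adjusted p = 0.0661 with an estimated correlation), with the B lineage factor Ebf1 at -4.13 ± 0.6. Myeloid granule genes were higher in 1 and lower in 7 of 14 (8 lower adjusted over the list alone; camera adjusted p = 5.41e-10, and adjusted p = 0.0677 with an estimated correlation). Mpo went from 10.4 ± 0.28 to 8.28 ± 0.12 (edgeR adjusted p = 1.49e-07), and the monocyte factor Irf8 fell by 2.02 ± 0.18 on the log2 scale.

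Erythroid genes rose in 7 of 11 (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 6.97e-07, and adjusted p = 0.0717 with an estimated correlation). The carbonic anhydrase Car1 gained 3.47 ± 0.5, the factor Klf1 2.73 ± 0.44 and the receptor Epor 2.02 ± 0.33 (edgeR adjusted p = 0.00674, 0.00185 and 0.00164). Megakaryocyte genes rose in 7 of 12 (9 adjusted over the list alone; camera adjusted p = 2.84e-07, and adjusted p = 0.195 with an estimated correlation), with Vwf at 2.11 ± 0.23. HSC markers rose in 12 of 19 (15 adjusted over the list alone; camera adjusted p = 2.97e-09, and adjusted p = 0.0682 with an estimated correlation), with Tie1 at 1.1 ± 0.13. Macrophage markers fell in 4 of 8 (camera adjusted p = 0.000432, and adjusted p = 0.275 with an estimated correlation), with Cd5l at -4.48 ± 0.72. The wild-type libraries had length correlations of -0.38, -0.31, -0.37 and 0.23 and the labelled knockouts 0.17, 0.1, 0.22 and 0.37. Y-linked reads were found in 2 of 4 wild-type and 4 of 4 knockout libraries. With the length correlation in the model edgeR called 280 genes, and 86 with wild-type replicate 4 alone as the wild type, the others being below -0.3. EdgeR called 660, 742, 714 and 2343 genes without wild-type replicates 1, 2, 3 and 4, and 877 without knockout replicate 2.

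**Figure D4:**
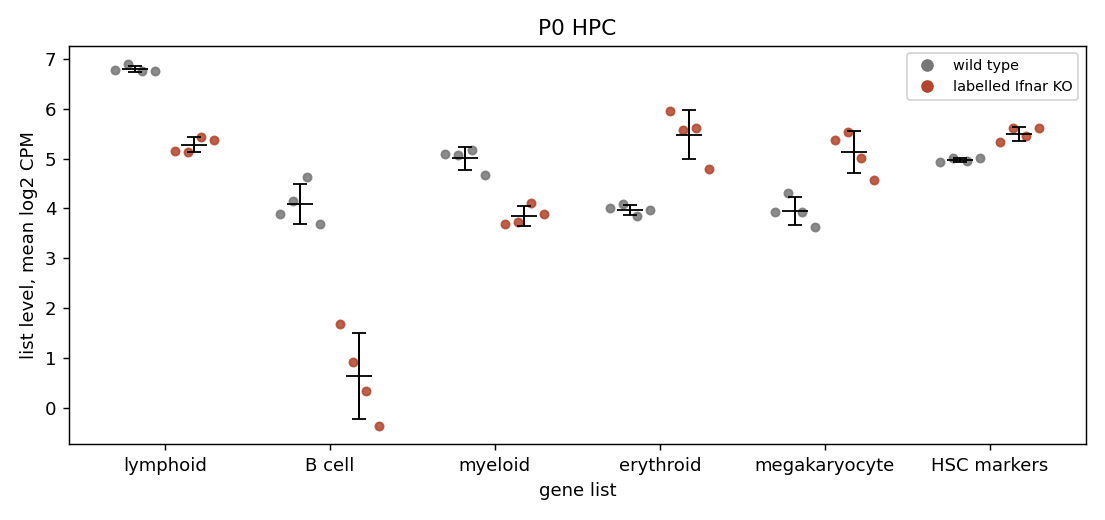
Levels of gene lists (log2 CPM) in P0 HPC, wild type and labelled Ifnar knockout. Each dot is a library, and bars give the mean ± SD of the group.

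The HSC and HPC responses to the labelled knockout shared the interferon genes and parted in the lineage genes. Among 12731 genes tested in both, 110 were lower in both (6.7 if independent) and 1, the translation factor Eif4b, was higher in both (1.45 if independent). In opposite directions edgeR called 6. The log2 fold changes had a Pearson correlation of 0.42 (0.25 without the interferon list) and a Spearman correlation of 0.12. The effects differed in 301 of 17191 genes by edgeR, 120 with a higher and 181 with a lower effect in HSC. Lymphoid priming had 6 of 15 higher (12 adjusted over the list alone; camera adjusted p = 1.03e-14), and Mpo stood at 2.5 ± 0.26. Erythroid genes had 5 of 14 lower (6 adjusted over the list alone; camera adjusted p = 1.39e-07), with Gata1 at -3.4 ± 0.5 (edgeR adjusted p = 0.00116). HSC markers had 7 lower (15 adjusted over the list alone; camera adjusted p = 1.15e-11) and megakaryocyte genes 4 of 13 (8 adjusted over the list alone; camera adjusted p = 5.37e-10), with Vwf at -2.01 ± 0.3. The interferon genes had 3 higher (6 adjusted over the list alone; camera adjusted p = 0.000225, and adjusted p = 0.57 with an estimated correlation). HSC libraries held 37.039 to 46.303 M reads and HPC libraries 11.683 to 14.72 M, so cell type and depth cannot be told apart. EdgeR called 194 genes without HPC wild-type replicate 1 and 620 without replicate 4.

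At P14, HPC of Ifnar heterozygotes with Flt3 ITD had more RNA of STAT5 targets. Socs2, a STAT5 target, rose from 2.99 ± 0.53 to 6.98 ± 0.35 (3.96 ± 0.25; edgeR adjusted p = 4.77e-08). Of 17464 genes, edgeR called 483 higher and 412 lower (4 libraries against 4). STAT5 targets rose in 6 of 10 (7 adjusted over the list alone; camera adjusted p = 3.1e-11), with Cish at 1.92 ± 0.27 and the kinase Pim1 at 1.23 ± 0.22. Myeloid granule genes had 2 higher and 2 lower of 15, with a median of -0.296 and an upward camera sign (camera adjusted p = 0.423), Irf8 and the receptor Csf1r being the higher. Macrophage markers had 1 higher of 8 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.793), and their list level went from 1.92 ± 0.2 to 0.94 ± 0.74. Irf8 gained 3.19 ± 0.29, Csf1r 2.39 ± 0.42, the lipid receptor S1pr3 3.66 ± 0.46 and the macrophage marker Adgre1 3.69 ± 0.28 (edgeR adjusted p = 4.53e-06, 0.00367, 0.000183 and 5.92e-07). Genes of interferon response rose in 31 (47 adjusted over the list alone; camera adjusted p = 1.23e-20, and adjusted p = 0.189 with an estimated correlation), from a list level of 4.98 ± 0.36 to 6.18 ± 0.72 (exact permutation p = 0.05714). Irf7 gained 2.23 ± 0.35 and the guanylate-binding Gbp3 1.42 ± 0.2. MAPK feedback fell in 2 of 9 (7 adjusted over the list alone; camera adjusted p = 0.000251, and adjusted p = 0.0833 with an estimated correlation), with Dusp6 at -1.63 ± 0.31. The heterozygotes with wild-type Flt3 had length correlations of -0.5, 0.53, -0.58 and -0.47, and those with ITD 0.41, 0.36, 0.13 and 0.09. With the length correlation in the model edgeR called 215 genes. Without the 4 P14 libraries below -0.3, which left 1 heterozygote library with wild-type Flt3, edgeR called 141. EdgeR called 5783, 281 and 357 genes without wild-type Flt3 replicates 2, 3 and 4, and 335, 380, 267 and 498 without ITD replicates 1, 2, 3 and 4.

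In Ifnar knockouts, Flt3 ITD also came with higher STAT5 targets, and no gene of the interferon list was called by edgeR. Socs2 gained 3.83 ± 0.24 (edgeR adjusted p = 5.34e-08), Slfn2 3.23 ± 0.31, Ifitm1 2.92 ± 0.25 and Cd48 1.34 ± 0.15. Of 17464 genes, edgeR called 113 higher and 54 lower (5 libraries against 4). STAT5 targets were higher in 3 and lower in 1 of 10 (6 higher adjusted over the list alone; camera adjusted p = 6.8e-12). MAPK feedback was higher in 1 and lower in 3 of 9 (8 lower adjusted over the list alone; camera adjusted p = 8.6e-11), with Dusp6 at -2.2 ± 0.29, the factor Etv5 at -2.45 ± 0.4 and Spred2 at -1.02 ± 0.17. Interferon-response genes had 0 called by edgeR (camera adjusted p = 0.000632 with a downward sign, and adjusted p = 0.62 with an estimated correlation). Between the Flt3 ITD effects in heterozygotes and knockouts, 68 genes were higher in both (3.13 if independent), 35 lower in both (1.27 if independent) and 0 opposite by edgeR, while all log2 fold changes had a Pearson correlation of 0.02 and a Spearman correlation of -0.23. The length correlations were 0.07, 0.32, 0.05, -0.16 and -0.42 with ITD and 0.43, 0.39, 0.48 and 0.31 without. Without the 4 P14 libraries below -0.3 edgeR called 354 genes.

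**Figure D5:**
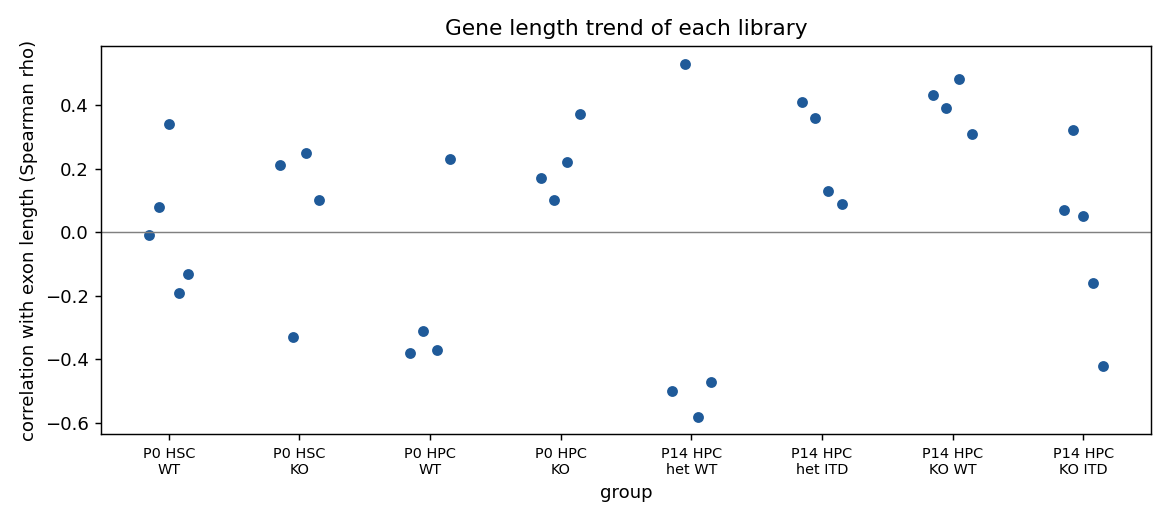
Gene length correlation (Spearman's rho) of each library of the genotype series, by group. It is taken across genes between exon length and the library's deviation from the mean of its part of the series.

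Among HPC with wild-type Flt3 at P14, labelled Ifnar knockouts had less RNA of MHC class I genes and of some interferon-response genes than heterozygotes. Rtp4 fell by 4 ± 0.39 and Ifi27 by 3.83 ± 0.26 on the log2 scale (edgeR adjusted p = 2.62e-05 and 3.09e-07). Of 17464 genes, edgeR called 212 higher and 621 lower (4 libraries against 4). The interferon response list fell in 27 (37 adjusted over the list alone; camera adjusted p = 5.94e-27, and adjusted p = 0.102 with an estimated correlation), from a list level of 4.98 ± 0.36 to 3.3 ± 0.12 (exact permutation p = 0.02857, the smallest possible). MHC class I fell in 10 (11 adjusted over the list alone; camera adjusted p = 4.68e-09), with B2m at -1.16 ± 0.21. Lymphoid priming fell in 4 (5 adjusted over the list alone; camera adjusted p = 0.00126, and adjusted p = 0.237 with an estimated correlation), with the receptor Il7r at -2.72 ± 0.4 and Dntt at -1.59 ± 0.25. B cell markers fell in 2 of 7 (5 adjusted over the list alone; camera adjusted p = 8.27e-05, and adjusted p = 0.0674 with an estimated correlation), with Cd79a at -2.93 ± 0.53. HSC markers rose in 3 (11 adjusted over the list alone; camera adjusted p = 0.000119, and adjusted p = 0.23 with an estimated correlation), with Mecom at 1.4 ± 0.3 and Mllt3 at 0.81 ± 0.15. The length correlations were -0.5, 0.53, -0.58 and -0.47 in heterozygotes and 0.43, 0.39, 0.48 and 0.31 in knockouts. With the length correlation in the model edgeR called 24 genes, and 11 without the libraries below -0.3, which left 1 heterozygote library. EdgeR called 60, 6233, 54 and 205 genes without heterozygote replicates 1, 2, 3 and 4, and 61, 47, 68 and 41 without knockout replicates 1, 2, 3 and 4.

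With Flt3 ITD, labelled Ifnar knockouts had far less of the interferon response. Ifit1 fell by 6.12 ± 0.52, Usp18 by 5.4 ± 0.43 and Rtp4 by 5.29 ± 0.38 on the log2 scale (edgeR adjusted p = 1.88e-06, 8.28e-07 and 1.74e-07). Of 17464 genes, edgeR called 373 higher and 337 lower (5 libraries against 4). The interferon genes fell in 53 (56 adjusted over the list alone; camera adjusted p = 3.12e-143), from a list level of 6.18 ± 0.72 to 3 ± 0.13 (exact permutation p = 0.007937, the smallest possible). MHC class I fell in 11 (13 adjusted over the list alone; camera adjusted p = 8.44e-37), with Tap1 at -1.87 ± 0.18. HSC markers rose in 6 of 20 (10 adjusted over the list alone; camera adjusted p = 3.75e-08, and adjusted p = 0.0833 with an estimated correlation), with Procr at 1.48 ± 0.2, Esam at 1.71 ± 0.33 and the factor Hlf at 1.03 ± 0.18. Lymphoid priming fell in 4 of 15 (6 adjusted over the list alone; camera adjusted p = 5.1e-06, and adjusted p = 0.0717 with an estimated correlation), with Il7r at -3.33 ± 0.39. B cell markers also fell, in 2 of 7 (5 adjusted over the list alone; camera adjusted p = 0.000734, and adjusted p = 0.112 with an estimated correlation), from a list level of 2.81 ± 0.74 to 1.22 ± 0.34. Among 12871 genes tested here and in P0 HPC, 183 were lower in both knockout comparisons (17.2 if independent), 53 higher in both (18.1 if independent) and 8 opposite. EdgeR called 327 and 333 genes without ITD heterozygote replicates 1 and 3, and 400 and 362 without ITD knockout replicates 4 and 5.

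The Flt3 ITD effect differed between labelled Ifnar knockouts and heterozygotes in 2 of 17464 genes by edgeR, both lower in knockouts (5181 at an unadjusted p under 0.05). DESeq2 called 2408 and the strict filter gave 1355, so the number is uncertain. These were the survival gene Bcl2 (-1.67 ± 0.24, edgeR adjusted p = 0.0293) and Nlrc5, which activates class I genes (-3.22 ± 0.5, edgeR adjusted p = 0.0327). Genes of interferon response had 0 called by edgeR (40 lower adjusted over the list alone; camera adjusted p = 5.94e-20, and adjusted p = 0.194 with an estimated correlation). Without heterozygote wild-type Flt3 replicate 2, edgeR called 5582 genes, and without any other library 0 to 14.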

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

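The tests of macrophages at E18, of receptor signalling, of B cells in the wild-type sort, of the Ifnar genotype at P14 and of the interferon response to Flt3 ITD were chosen after the result they bear on was seen, as were the fits with the length correlation or the Y-linked level in the model.

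Interferon-response genes were higher in HSC at E18 than at E16. Macrophages in the E18 sort are argued against as the whole cause. Their markers had a median log2 fold change of 0.41 with 1 of 8 called higher by limma, against 1.2 for interferon genes. The permutation p (0.0016) took genes as independent. Sex is argued against, since all 47 interferon genes called higher were called with the Y-linked level in the model. Signalling through the interferon receptor stays open. Of these 47, 43 were lower in P0 HSC labelled Ifnar knockout (median -1.95), but so were 9 of the 11 other list members (Fisher p = 0.318), so this test does not decide. That comparison was added once the 43 were known. E18 and E16 share a code prefix. A change in which cells the sort took stays open.

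In P0 HPC labelled Ifnar knockout, the lymphoid list was lower and the erythroid list higher, the erythroid call being lost with an estimated correlation (adjusted p = 0.0717). The length trend is argued against as the whole cause, as the medians were -0.93 and 1.94 with the length correlation in the model and 13 lymphoid genes stayed under -0.5, although the count of all calls fell to 280. Sex is argued against, since against the wild-type libraries that hold Y-linked reads (1 and 3) the medians were -1.07 and 2.07 with 11 lymphoid genes called lower. B cells in the wild-type sort are argued against as the whole cause, since without Ighm, Il7r, Rag1, Rag2 and Dntt the lymphoid median was -0.7 with 8 called lower, and the myeloid median was -1. Whether the genotype itself may shift the lineages stays open. At P14 with Flt3 ITD, the list levels went from 6.26 ± 0.27 in heterozygotes to 5.32 ± 0.31 in knockouts (lymphoid) and from 1.37 ± 0.23 to 1.96 ± 0.32 (erythroid), but B cell markers fell too (2.81 ± 0.74 to 1.22 ± 0.34), so B cells in the sort stay open there. With wild-type Flt3, the levels went from 6.37 ± 0.37 to 5.86 ± 0.07 (lymphoid), 2.16 ± 0.64 to 2.1 ± 0.95 (erythroid) and 1.71 ± 0.71 to -0.16 ± 0.5 (B cell). The lymphoid and erythroid medians were -0.69 and 0.04. A different mix of cells in the sort was not tested apart from these markers.

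At P14, more genes were called for Flt3 ITD in Ifnar heterozygotes (895) than in labelled knockouts (167). With the length correlation in the model the counts were 215 and 128, and the order reversed with only the groups compared (164 and 307) or only libraries above -0.3 (141 and 354). Much of the gap may lie with the length trend, and the trend and genotype cannot be told apart because 3 of 4 heterozygote libraries with wild-type Flt3 carry it. The interferon list rose by 1.2 with ITD in heterozygotes and changed by -0.3 in knockouts (permutation p = 0.0024 for the difference). Its members were 3.46% of the calls in heterozygotes, too few to account for most of them, and an indirect effect stays open.

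Effects that differed between groups, each by a test of the difference itself, were the change from E16 to Adult between HSC and HPC (605 genes by limma), the labelled knockout effect between P0 HSC and HPC (301 genes by edgeR), and the Flt3 ITD effect between labelled Ifnar genotypes (2 genes by edgeR, 5181 at an unadjusted p under 0.05, 2408 by DESeq2 and 1355 with the strict filter). Other splits of the libraries within each cell type or genotype also break the main effects, so they are a rough guide here. Of 100 splits each, 8, 3 and 4 gave as many calls, with highest other counts of 2941, 8983 and 30. These splits do not decide whether chance can be excluded for the 301 and the 2, and it is not excluded for the 605. Counts several times the real one point to a structure of the samples.

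For the other comparisons, each possible split was counted once, or 100 were drawn. In HSC, 1 of 35 splits (the real one) gave as many calls for Adult against E16 (3305, highest other 3), E16 against E14 (7, highest other 5), E18 against E16 (736, highest other 87), P0 against E18 (651, highest other 272), P7 against P0 (818, highest other 6), P14 against P7 (232, highest other 2) and Adult against P14 (710, highest other 64). In HPC it was 1 of 35 for Adult against E16 (3979, highest other 1106), P0 against E16 (485, highest other 43) and P7 against P0 (218, highest other 0), 3 of 100 for P14 against P7 (1458, highest other 2447) and 1 of 100 for Adult against P14 (4274, highest other 3846). It was 1 of 100 for HSC against HPC (9277, highest other 7). For the labelled knockout it was 1 of 100 in P0 HSC (186, highest other 15), 1 of 35 in P0 HPC (1400, highest other 0), and 1 of 100 at P14 with Flt3 ITD (710, highest other 247). For Flt3 ITD in knockouts it was 1 of 100 (167, highest other 3). The splits make chance less likely for most of these but do not exclude it, since 1 of 35 is the lowest possible and uncorrected. E16 against E14 in HSC kept 0 calls by limma with only its groups fitted. In HPC, splits of P14 against P7 called more than the real one. So did splits for Flt3 ITD in heterozygotes (3 of 35, 895 calls, highest other 3234) and the labelled knockout with wild-type Flt3 (5 of 35, 833 calls, highest other 3636). These point to a structure of the samples.

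Single libraries stood apart from their group in 31 of 527 sets of values, where chance gives about 1 in 20, by a gap that took up most of the range of the group. In total reads these were P0 HSC wild type 2 (37.039 M, others 44.015 to 46.229) and P14 knockout with wild-type Flt3 2 (90.359 M, others 73.468 to 74.55). For Ifnar1 they were P0 HPC wild type 4 (6.31) and knockout 4 (6.24), and for Ifnar2 HSC P0 1 (3.55) and P0 HSC knockout 2 (5.5). For Flt3 they were P0 HSC wild type 4 (7.33) and knockout 4 (8.12), P0 HPC knockout 1 (8.57), and P14 knockout with wild-type Flt3 1 (8.98). In HSC list levels, they were MHC class I in P0 1 (5.3), MHC class II in E16 1 (1.33), the Lin28b axis in P7 1 (2.8), macrophage in E16 1 (-0.02) and P0 wild type 4 (-0.51), T and NK cell in P0 2 (3.27) and Adult 2 (4.29), and B cell in P0 knockout 2 (-0.52). In HPC of the age series, they were lymphoid and S phase in Adult 4 (6.98 and 7.49), erythroid in P7 1 (2.48), megakaryocyte in P0 4 (3.3), and STAT5 targets and neutrophil in P7 3 (4.25 and -0.85). At P14 they were MHC class II in ITD heterozygote 1 (5.91), myeloid granule in wild-type Flt3 heterozygote 1 (6.65, others 2.8 to 3.32), erythroid in ITD knockout 3 (2.52), and megakaryocyte and glycolysis in wild-type Flt3 knockout 1 (2.57 and 7.67). In the length correlation they were P0 HPC wild type 4 (0.23, others -0.38 to -0.31) and wild-type Flt3 heterozygote 2 (0.53, others -0.58 to -0.47).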

How the results depend on the processing

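The fits with edgeR on recovered reads, pseudocounts of 0.1 and 1, no scaling of the RPKM, the length correlation or Y-linked level in the model, and only libraries above -0.3 were chosen after the data were seen. Of 1150 genes named in a comparison, 1138 had the same direction under each setting that gave a value, and 683 were called under each. Of 452 counts of calls under another setting, 326 lay within 1.5 times the count reported. Except where said, the cause was not tested.

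With DESeq2, calls were 64 for HSC E16 against E14, 1111 for E18 against E16 and 394 for P14 against P7. In HPC they were 877 for P0 against E16 and 416 for P7 against P0. For the labelled knockout they were 336 in P0 HSC, 759 for the difference between cell types, 3097 at P14 with wild-type Flt3 and 1376 with ITD. For Flt3 ITD they were 2656 in heterozygotes, 428 in knockouts and 2408 for the difference. In the age difference between cell types, Igkc (6.54), Igf2 (1.15), H19 (2.05) and Clec1a (-0.31) reversed. EdgeR on recovered reads also reversed Igf2 (1.02), H19 (1.93) and Clec1a (-1.08) there, and a pseudocount of 0.1 reversed H19 (0.52).

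With no filter, calls were 14, 471 and 143 for HSC E16 against E14, E18 against E16 and P14 against P7, and 4 for the Flt3 ITD difference. The strict filter, which tests fewer genes, gave 314 for HPC P0 against E16, 1682 for Flt3 ITD in heterozygotes, 2195 for the knockout with wild-type Flt3 and 1355 for the Flt3 ITD difference. With no scaling of the RPKM, HSC E16 against E14 had 13.

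With a replicate block, although replicate numbers do not pair libraries, calls were 4 for HSC E16 against E14, 1585 for Flt3 ITD in heterozygotes, 1504 and 459 for the knockout with wild-type Flt3 and ITD, and 1 for the Flt3 ITD difference. With only the groups compared, which leaves fewer libraries to estimate the spread, HSC calls were 0 by limma for E16 against E14 (1250 at an unadjusted p under 0.05), 134 for P0 against E18 and 417 for P7 against P0. In HPC they were 170 for P0 against E16, 640 for P7 against P0 and 2657 for Adult against P14. At P14 they were 164 and 307 for Flt3 ITD in heterozygotes and knockouts, and 44 and 1398 for the knockout with wild-type Flt3 and ITD.

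The length correlation in the model gave 462 calls for HSC E18 against E16, and in HPC 926 for P0 against E16, 369 for P7 against P0, 2422 for P14 against P7 and 1930 for Adult against P14. They were 280 for the knockout in P0 HPC, 215 for Flt3 ITD in heterozygotes, 24 for the knockout with wild-type Flt3 and 0 by edgeR for the Flt3 ITD difference (491 at an unadjusted p under 0.05). With the Y-linked level, they were 1868 for HSC Adult against E16, 417 for HPC P14 against P7, 78 for the knockout with wild-type Flt3 and 0 by edgeR for the Flt3 ITD difference (5127 at an unadjusted p under 0.05), and Uty (0.31) and Eif2s3y (0.3) reversed in HSC Adult against E16, as a covariate made of these genes would do.

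With only libraries above -0.3, which left 1 wild-type library in P0 HPC and 1 heterozygote library with wild-type Flt3 at P14, the lone library was assumed to vary like the others. Calls were 2258 for HPC Adult against P14, 86 for the knockout in P0 HPC, 141 and 354 for Flt3 ITD in heterozygotes and knockouts, 11 for the knockout with wild-type Flt3 and 0 by edgeR for the Flt3 ITD difference (836 at an unadjusted p under 0.05). Ndufa4 (0.06) reversed in the P0 HPC knockout, and Cdk1 (0.17), Pcna (0.06), Gins2 (0), Ndufb5 (0.01) and Ndufb8 (0.03) in the knockout with wild-type Flt3.

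Of 228 list calls, 67 were made with an estimated correlation. With fry 220 lists were called (177 of the same), with RLE factors 225 (225 of the same) and with the replicate block 220 (215 of the same). With a log2 fold threshold of 2, the share of the change for higher genes in HSC was -2.381% at E14, 18.7% at E18, 28.03% at P0, 37.85% at P7 and 61.22% at P14, and for lower genes -1.909% at E14, 19.53% at E18, 12.91% at P0 and 58.69% at P14. For lower genes in HPC it was 17.2% at P0, 37.28% at P7 and 56.41% at P14.

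Leaving out each library in turn gave 2 to 7 calls for HSC E16 against E14, 425 to 620 for E18 against E16, 383 to 670 for P0 against E18, 463 to 776 for P7 against P0 and 124 to 202 for P14 against P7. In HPC it gave 2535 to 3687 for Adult against E16, 232 to 527 for P0 against E16, 112 to 179 for P7 against P0 and 542 to 1612 for P14 against P7. It gave 660 to 2343 for the knockout in P0 HPC and 194 to 620 for the difference between cell types. At P14 it gave 267 to 5783 for Flt3 ITD in heterozygotes, 41 to 6233 and 327 to 695 for the knockout with wild-type Flt3 and ITD, and 0 to 5582 for the Flt3 ITD difference. The 5783, 6233 and 5582 were without wild-type Flt3 heterozygote 2, whose length correlation differs from the rest of its group.

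Without each replicate in turn, the share of the E16 to Adult change in percent, HSC genes higher in Adult, at E14, was -5.035 to -1.23, and the share of the E16 to Adult change in percent, HSC genes higher in Adult, at P0, was 34.21 to 37.39. The share of the E16 to Adult change in percent, HSC genes higher in Adult, at P14, was 64.28 to 67.63, and the share of the E16 to Adult change in percent, HSC genes lower in Adult, at E18, was 24.88 to 30.22. Likewise the share of the E16 to Adult change in percent, HSC genes lower in Adult, at P7, was 38.16 to 42.57, and the share of the E16 to Adult change in percent, HPC genes lower in Adult, at P0, was 18.62 to 26.2. Last, the share of the E16 to Adult change in percent, HPC genes lower in Adult, at P7, was 34.96 to 42.75, and the share of the E16 to Adult change in percent, HPC genes higher in Adult, at P7, was 48.56 to 58.01.

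What depth limits in low genes was not tested, since the simulated changes were set in genes expected above 50 reads. In these, 35% of genes changed 2-fold were recovered for the age difference between cell types and 34% for the knockout difference between cell types, against 96% for HSC against HPC, where the contrasts differ and not the depth alone.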

Other observations

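The length and Y-linked values and the comparisons within code prefixes in this part were chosen after the data were seen.

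In the P0 HSC of the genotype series, wild-type libraries (Xist 4.97 ± 0.69 and Ddx3y 6.05 ± 0.14) and knockouts 1 to 3 held reads of both Xist and Y-linked genes, while knockout 4 held almost no Xist (-0.41). The labels give no sex. In the age series, 0 of 4 HSC Adult and 2 of 4 HSC P14 libraries held Y-linked reads, and so did 3 of 4 HPC Adult and 1 of 5 HPC P14 libraries.

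Gene length went with the genotype comparisons to different degrees. Spearman's rho between exon length and log2 fold change was 0.01 for the labelled knockout in P0 HSC and 0.27 in P0 HPC. At P14 it was 0.36 for the knockout with wild-type Flt3, -0.17 with ITD, 0.3 for Flt3 ITD in heterozygotes and -0.27 in knockouts. For the knockout with wild-type Flt3, the median exon length was 5212 for genes called higher and 1831 for genes called lower.

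Tpm3-rs7 moved by large amounts between some groups. It was 3.97 ± 0.39 higher in HSC at P7 than at P0, and in HPC it was 4.76 ± 0.7 higher at P7 than at P0, -4.7 ± 0.63 at P14 against P7 and 5 ± 0.63 in Adult against P14. It was also 3.65 ± 0.21 higher in P0 HSC labelled knockout. No explanation was tested.

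Within code prefixes, HSC E18 against E14 gave 1373 limma calls, with 44 interferon genes higher, and Adult against P0 gave 10 interferon genes higher and 5 lower.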
